A study of Homo sapiens with 5 samples.

How the data were processed

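RNA immunoprecipitation followed by sequencing (RIP-seq) was done on LTAD cells, a human prostate cancer line kept in androgen-depleted, charcoal-stripped medium, per the labels' protocols. Cells received the DMSO vehicle or the small molecule No.10-3 at 5 µM. RNA bound to PSF, the RNA-binding protein encoded by SFPQ, was recovered from lysates with a commercial RIP kit, and libraries were made with a stranded Illumina kit, per the labels' protocols. The series has 5 samples: 1 vehicle input, 1 No.10-3 input, 1 vehicle PSF-RIP and 2 No.10-3 PSF-RIP samples. The labels give no control immunoprecipitation among these 5 samples. They do not say whether the 2 No.10-3 PSF-RIP samples came from separate cultures. The p-values for single genes rest only on the spread between those libraries, pooled as a trend over genes, which may be technical. Camera and permutation p-values also rest on the spread over genes, which are not independent replicates.

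The authors deposited 1 table with a row per Entrez gene and, for each library, a whole-number read count, a gene length and an FPKM value. TopHat2 2.1.0, Bowtie2 2.2.6, Bowtie and the hg19 build are named in the submitters' processing notes, without their roles. The counting tool, its strand setting, its treatment of reads that map to several places and the gene annotation are not given in the sources used here. The deposited counts are whole numbers and were taken as raw counts, which the sources used here do not state. The deposited FPKM values equal the count divided by the gene length and by the library's total gene count, to within a relative deviation of 4.81e-08, and were used only for that check. The 2 count columns taken as No.10-3 PSF-RIP libraries are named for the compound, without PSF or RIP. They were assigned by elimination, since 2 other columns are named input and 2 samples are titled input. Per the file headers, 2 columns of counts and 2 of FPKM belong to input libraries. Their names do not tell the vehicle input from the No.10-3 input, so these columns were not used in any step. The planned comparisons of PSF-RIP with input, of the 2 inputs, of the change in recovery over input and of PSF-bound genes were therefore not analysed here. A difference between PSF-RIP libraries can come from recovery by PSF or from the amount of the RNA in the cells, and the 2 could not be separated.

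The table has 25702 genes, of which 1962 carry no symbol and took 0.444% to 0.504% of a library's counts. These were kept, since they have an Entrez ID. Biotypes came from a RefSeq gene table of a later assembly, matched on Entrez ID for 23696 genes, and none of its coordinates were used. Each library is 1 column, and no library was pooled.

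The 2 No.10-3 PSF-RIP libraries were compared with the single vehicle PSF-RIP library. Genes with a mean of at least 1 CPM (counts scaled to the same total in each library) over the 3 PSF-RIP libraries were tested, 13766 in all. The filter had been planned over all 5 libraries. Counts were scaled with edgeR's TMM factors (edgeR 4.0.16, R 4.3.3) and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05. The treated pair gives the only estimate of spread, with 1 residual degree of freedom per gene, moderated across genes to the common trend. The vehicle library was assumed to vary like that pair. The standard error (SE) of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. It need not reflect a gene's own replicates. GSKIP, with replicates -0.12 log2 units apart, had an SE of 0.92, and PTGER4, with replicates -2.37 apart, had 0.93. Log2 changes of each treated library from vehicle were taken from log2 CPM with a prior count of 2, which understates the change of low genes, and genes at least 2-fold away from vehicle in the same direction in both treated libraries were counted. Because both changes share the vehicle library, 100 sets of 3 unchanged libraries with the same means, sizes and dispersions were simulated. They give the agreement that arises with no effect if the vehicle library varies like the treated pair.

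Before the data were examined, 25 gene lists, the test and the rule for named genes were fixed. The lists reported were DBHS and paraspeckle proteins, nuclear-retained long noncoding RNAs, snoRNA host long noncoding RNAs, prostate long noncoding RNAs, androgen-activated genes, core spliceosome, SR proteins, hnRNP proteins, DNA repair, cell cycle and mitosis, cytosolic ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, small structured noncoding RNAs, unfolded protein and integrated stress response, heat shock and NRF2 response, p53 targets and apoptosis, cholesterol synthesis, glycolysis and hypoxia, aryl hydrocarbon receptor targets, neuroendocrine markers, luminal epithelial markers, basal and stromal markers, and abundant housekeeping mRNAs. The result of 1 further list and of 3 single genes that the rule names is not reported here. The lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, as 1 family of 25, and again with an estimated correlation. The latter leaves camera 1 residual degree of freedom, so it could hardly call any list. For each treated library, the percentile of a list's median among 10000 random lists of the same size, drawn to match its members over 20 bins of expression, was taken as well. The rule names, among genes with a mean of at least 5 CPM and at least 200 nt long, the 10 highest and 10 lowest changes that pass the test and are at least 2-fold in both treated libraries. Where fewer pass, each direction is filled to 10 by the smaller of the 2 treated libraries' absolute log2 changes, as values only. SFPQ, NONO, PSPC1, NEAT1 and MALAT1 and up to 4 members of each list with the largest change are added.

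The tests were tried on simulated data drawn from the real means, library sizes and dispersions. In 5 runs with 200 changed genes each among 13766, edgeR recovered 1.6% of genes changed 2-fold, 19.6% of those changed 4-fold, 78.0% of those changed 8-fold and 94.4% of those changed 16-fold, with 26 false calls over the 5 runs. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery among lower genes was not measured. Camera called 0 of 125 unchanged lists, and the cell cycle list in 4 of 5 runs in which its genes were set to a log2 change of -0.5. The simulated genes vary independently, which real lists need not do.

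Alternatives were median-ratio and upper-quartile scaling, no filter on low counts, a filter at a mean of 5 CPM, leaving out mitochondrially encoded and small structured RNAs, DESeq2 1.42.0, thresholds of 1.5-fold and 4-fold, leaving out each treated replicate, and camera with an estimated correlation. Prior counts of 0.5 and 5 and the removal of a length trend, a lowess curve of protein-coding genes' log2 CPM against length with a span of 0.3 in each library, were added after seeing the data. RNAs shorter than the protein-coding genes took the value at the curve's short end, which is not a trend measured on such RNAs. Planned pseudocounts for normalized values were not needed, since counts were tested. Intervals of shares are 95% Wilson intervals, and intervals of ratios of low counts are exact binomial. Both cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts, or 0.891 to 1.97 CPM depending on the library.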

Results

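PSF-RIP libraries of LTAD prostate cancer cells were sequenced with vehicle (1 library) and with 5 µM No.10-3, a small molecule known here only by its code name (2 libraries, replicates 1 and 2). PSF, encoded by SFPQ, is a nuclear RNA-binding protein of the DBHS family and, with NONO and PSPC1, a component of paraspeckles, the nuclear bodies built on the long noncoding RNA NEAT1. By its title, the series asks whether a small molecule alters which RNAs PSF binds. The vehicle library held 2181770 counts over genes, the No.10-3 library of replicate 1 held 1519362 and that of replicate 2 held 3368252. Between 14699 and 15699 genes had a count above 0 per library, and the median count of a tested gene was 57 with vehicle, 36 in replicate 1 and 99 in replicate 2.

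The libraries differed in the kinds of RNA they held. Nuclear protein-coding genes took 76.1% of counts with vehicle (95% Wilson interval 76.0 to 76.2%), 73.6% in replicate 1 (73.6 to 73.7%) and 82.1% in replicate 2 (82.1 to 82.2%). Mitochondrially encoded genes took 6.91% with vehicle (6.88 to 6.94%), 12.2% in replicate 1 (12.1 to 12.2%) and 9.49% in replicate 2 (9.46 to 9.52%). Small nucleolar RNAs (snoRNAs), which guide modification of ribosomal RNA, took 3.04% with vehicle (3.01 to 3.06%), 1.69% in replicate 1 (1.67 to 1.71%) and 0.259% in replicate 2 (0.254 to 0.265%). Across 13766 genes, which are not independent replicates, log2 CPM of the treated pair correlated with a Pearson's r of 0.924, against 0.947 for vehicle with replicate 1 and 0.915 for vehicle with replicate 2. Replicates 1 and 2 lay at least 2-fold apart at 2359 genes, vehicle and replicate 1 at 1620, and vehicle and replicate 2 at 2607. The difference between the treated replicates thus lay between their differences from vehicle. Counts of each pair differed by more than sampling noise (chi-square per degree of freedom of 9.85 to 38.1), which does not tell whether the treated pair came from separate cultures.

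With No.10-3, PSF-RIP held relatively less of the RNAs that host snoRNAs and of cell cycle and mitosis mRNAs, and relatively more of the RNAs encoded in mitochondria, each in both treated libraries. Among random lists of like expression, their medians in replicates 1 and 2 were at percentiles 0.01 and 0, 0 and 0.09, and 100 and 97.99. Both percentiles of a list use the same vehicle library, so their agreement is not independent replication. The random lists also hold unrelated genes, while members of a list may vary together. Expression was matched by bin only, so random lists for the mitochondrially encoded genes (median 4096 CPM) may hold genes of lower expression. By these percentiles, the other lists called rested more on 1 library. SR splicing factor mRNAs (percentiles 0 and 19.05) and DNA repair mRNAs (0 and 26.06) were lower as lists mostly in replicate 1. Targets of p53 (93.08 and 98.32) ranked higher in replicate 2, with median log2 changes of 0.26 in replicate 1 and 0.44 in replicate 2. Cholesterol synthesis mRNAs (99.89 and 89.39) ranked higher in replicate 1, but their median log2 difference of replicate 2 minus replicate 1 was only -0.04. Small structured noncoding RNAs and cytosolic ribosomal protein mRNAs were lower as lists through replicate 2, with medians close to vehicle in replicate 1. No single gene passed the test, and mRNAs of PSF's own family and of androgen-activated genes showed no change past it as lists or as genes. Members on the same side of vehicle in both treated libraries are given as counts only, since the shared vehicle library gives such agreement without an effect: of all 13766 tested genes, 4486 were lower in both and 4558 higher in both. The list calls rest on a preset correlation of 0.01 between genes, and 0 of the 9 held with an estimated one. With an estimated correlation camera has 1 residual degree of freedom and could hardly call any list (smallest unadjusted camera p = 0.132). That result therefore does not tell whether correlation between genes accounts for the calls, which stay unproven.

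edgeR's quasi-likelihood test called 0 of 13766 genes, with a smallest adjusted p of 0.140. An unadjusted p under 0.05 was reached by 563 genes, fewer than the 688.3 that chance would give, and DESeq2 called 0 genes, with 123 at an unadjusted p under 0.05. With the length trend removed from each library, a setting chosen after seeing the data, edgeR called 19 genes, all lower with No.10-3 and comprising 17 snoRNAs and 2 scaRNAs (small RNAs of the Cajal body). The called snoRNAs, of 88 to 149 nt, took a correction set by the shortest protein-coding genes. It moved the median log2 change of all 208 snoRNAs from -1.30 to -1.55, so these calls do not rest on a length trend measured in such RNAs. All 19 called RNAs differed widely between replicates and fell further in replicate 2. The gap was smallest for SNORA8, at -1.49 in replicate 1 and -3.47 in replicate 2, and largest for SNORA20, at -0.66 and -6.03. A total of 352 genes were at least 2-fold higher than vehicle in both treated libraries and 210 at least 2-fold lower. Simulated unchanged libraries that share 1 vehicle library gave 473.9 higher (range 416 to 526) and 299.8 lower (259 to 346), and both observed counts lay below these ranges. The simulation gave the vehicle library the dispersion of the treated pair, which may be too large for it. It therefore cannot tell how much of the observed agreement the shared vehicle library gave. Independent sets of the sizes found in each treated library alone would share 79.6 and 72.1 genes. Leaving out replicate 1 the counts were 1476 higher and 1131 lower, and leaving out replicate 2 they were 742 and 878. The correlation of the 2 sets of log2 changes across genes was 0.449, against 0.495 in simulation, and their covariance was 0.245 against 0.284.

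The genes named next had the largest log2 change by the smaller of their changes in the treated libraries and stand as values, since none passed the test (adjusted p of 0.614 to 0.998 by edgeR). TIMP2, which encodes a tissue inhibitor of metalloproteinases, stood at 22.4 CPM with vehicle and 88.1 ± 0.153 CPM with No.10-3 (SD, n = 2), a log2 change of 1.97 (SE 0.64). PGRMC1, a heme-binding membrane protein, stood at 31.6 CPM with vehicle and 114 ± 7.88 CPM with No.10-3, a log2 change of 1.86 (SE 0.62). HSD17B12, an enzyme of fatty acid elongation, had the largest log2 change of this set at 3.19 (SE 0.93), from 1.83 CPM with vehicle to 9.25 in replicate 1 and 23.7 in replicate 2. GSKIP was at 2.29 CPM with vehicle, 13.5 in replicate 1 and 12.4 in replicate 2, RNASE4 at 2.75 with vehicle and 14.3 ± 0.0822 with No.10-3, REPS2 at 2.75 and 12.4 ± 0.421, and C2orf69 at 4.12 and 19.3 ± 5.12. RNASE4 overlaps the ANG gene, so its reads are uncertain. DIPK1A had only 3 counts with vehicle, which puts the ratio of replicate 1 to vehicle at 5.18 (exact interval 1.33 to 29.3) and that of replicate 2 at 5.42 (1.67 to 27.9). The transcribed pseudogenes TPI1P2, at 1.83 CPM with vehicle and 9.80 ± 0.215 with No.10-3, and SUMO1P3, at 1.83 and 8.96 ± 0.595, may share reads with their parent genes. Vehicle counts were also low for HSD17B12, TPI1P2 and SUMO1P3 (4 each), GSKIP (5), RNASE4 and REPS2 (6 each) and C2orf69 (9). The SD of the treated pair does not cover the error of these vehicle values, so the size of the changes is uncertain.

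Among the lowest with No.10-3, SAMD11 stood at 80.6 CPM with vehicle and 26.1 ± 2.26 CPM with No.10-3, a log2 change of -1.63 (SE 0.57). DNMT3B, a de novo DNA methyltransferase, stood at 31.1 CPM with vehicle and 11.4 ± 0.944 with No.10-3, a log2 change of -1.45 (SE 0.64). SNHG5, a long noncoding RNA whose introns carry snoRNAs, stood at 19.2 CPM with vehicle and 6.65 ± 0.349 with No.10-3, a log2 change of -1.52 (SE 0.70). LIN7B was at 35.7 CPM with vehicle, 13.5 in replicate 1 and 12.4 in replicate 2, AMH, the anti-Müllerian hormone gene, at 24.3 with vehicle and 9.04 ± 0.298 with No.10-3, and MRPL46, a mitochondrial ribosomal protein, at 25.7 and 9.94 ± 0.0205. A gene without a symbol in the table (Entrez ID 221016) was at 22.0 CPM with vehicle and 6.57 ± 1.24 with No.10-3. The transcribed pseudogenes SLC7A5P2 (11.9 CPM with vehicle and 3.22 ± 0.523 with No.10-3), PMS2P3 (27.0 and 8.76 ± 0.688) and HSD17B7P2 (27.5 and 10.6 ± 0.133) may likewise share reads with parent genes.

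**Figure D1:**
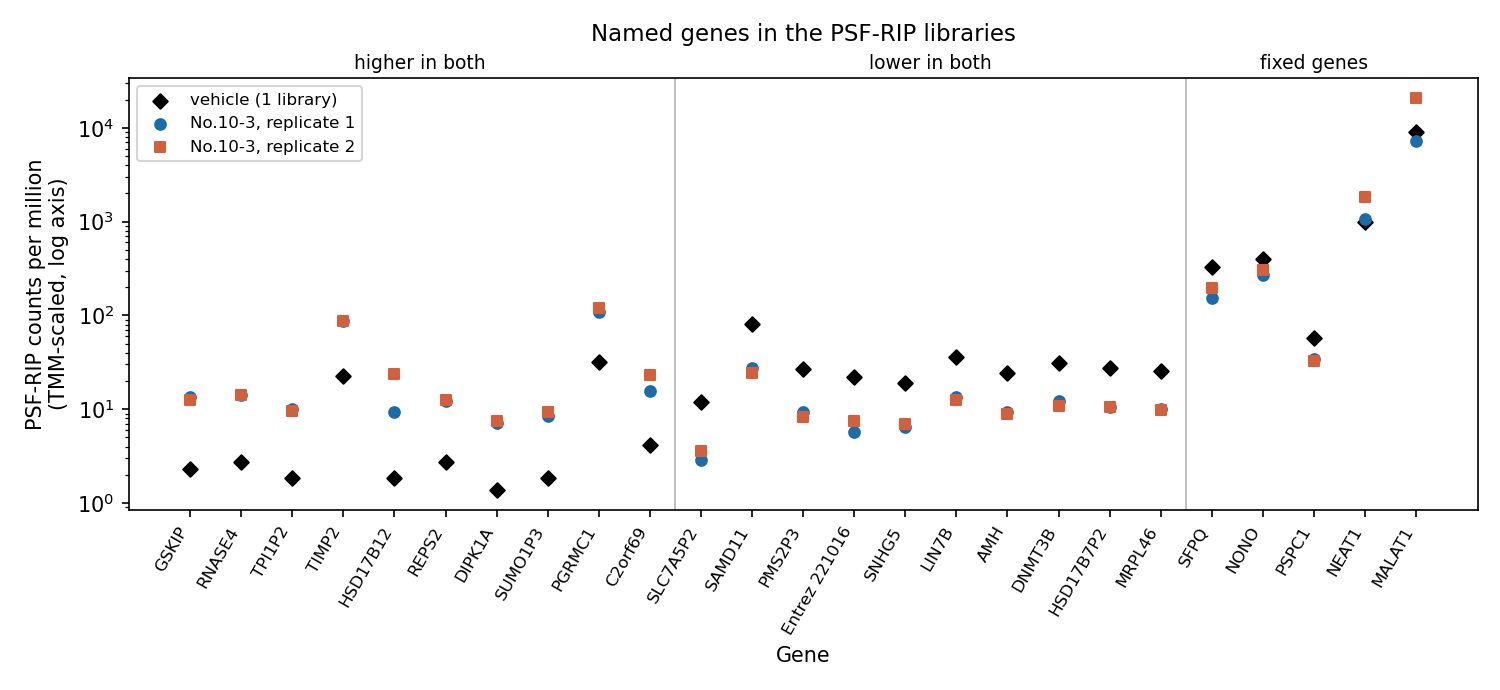
TMM-scaled CPM on a log axis for the 10 genes named as higher, the 10 named as lower and 5 genes fixed in advance, with 1 point per PSF-RIP library. TIMP2 stood at 22.4 with vehicle and about 88 in both treated libraries, and MALAT1 at 9014 with vehicle, 7148 in replicate 1 and 20962 in replicate 2.

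SFPQ mRNA itself stood at 324 CPM in PSF-RIP with vehicle and at 175 ± 33.1 CPM with No.10-3 (SD, n = 2), a log2 change of -0.89 (SE 0.58, adjusted p = 0.998 by edgeR). NONO stood at 401 CPM with vehicle and 288 ± 25.7 with No.10-3, and PSPC1 at 57.3 and 33.5 ± 0.934. The list of DBHS and paraspeckle proteins had a median log2 change of -0.44 in replicate 1 and -0.30 in replicate 2, with 13 of 20 members lower in both, and missed the threshold (camera adjusted p = 0.121). NEAT1 stood at 985 CPM with vehicle, 1055 in replicate 1 and 1817 in replicate 2. MALAT1, an abundant nuclear long noncoding RNA, went opposite ways, with a log2 change of -0.34 in replicate 1 and 1.22 in replicate 2.

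The snoRNA host long noncoding RNAs had a median log2 change of -0.61 in replicate 1 and -0.80 in replicate 2, with 10 of 14 lower in both (camera adjusted p = 0.00282; adjusted p = 0.809 with an estimated correlation). Besides SNHG5, SNHG7 stood at 81.5 CPM with vehicle and 40.8 ± 9.71 with No.10-3, and SNHG8 at 50.8 and 26.3 ± 0.0819. EPB41L4A-AS1 stood at 18.8 CPM with vehicle and 9.43 ± 2.27 with No.10-3. Cell cycle and mitosis mRNAs had medians of -0.60 in replicate 1 and -0.45 in replicate 2, with 25 of 36 lower in both and 3 higher in both (camera adjusted p = 5.39e-04; adjusted p = 0.809 with an estimated correlation). MCM2 and MCM5, subunits of the replicative helicase, stood at 39.4 and 38.5 CPM with vehicle and at 18.3 ± 1.29 and 17.5 ± 4.44 CPM with No.10-3. CCNB2, a mitotic cyclin, stood at 25.7 CPM with vehicle and 12.6 ± 1.70 with No.10-3. E2F1, a transcription factor of the G1/S transition, stood at 64.1 CPM with vehicle, 48.4 in replicate 1 and 20.1 in replicate 2.

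DNA repair mRNAs had medians of -0.57 in replicate 1 and -0.08 in replicate 2, with 17 of 31 lower in both (camera adjusted p = 0.0374; adjusted p = 0.809 with an estimated correlation). RAD54L, of homologous recombination, stood at 35.7 CPM with vehicle and 15.4 ± 4.71 with No.10-3, and LIG1, a DNA ligase, at 16.5 and 7.36 ± 0.657. CHEK2, a checkpoint kinase, stood at 21.1 CPM with vehicle and 10.3 ± 2.55 with No.10-3. The call was lost when only genes with a mean of at least 5 CPM were tested (adjusted p = 0.0816, against 0.0212 to 0.0816 over its 6 alternatives). SR protein mRNAs had medians of -0.61 in replicate 1 and -0.24 in replicate 2, with 13 of 20 lower in both (camera adjusted p = 0.0208; adjusted p = 0.809 with an estimated correlation). SRSF2 stood at 290 CPM with vehicle and 170 ± 14.8 with No.10-3, SRSF5 at 312 and 200 ± 17.7, and SRSF6 at 731 and 469 ± 23.9. CLK4, a kinase of SR proteins, stood at 35.7 CPM with vehicle, 12.8 in replicate 1 and 29.5 in replicate 2.

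Mitochondrially encoded genes were higher as a list, with medians of 0.87 in replicate 1 and 0.38 in replicate 2 and 14 of 15 higher in both (camera adjusted p = 0.00298; adjusted p = 0.809 with an estimated correlation). COX1 stood at 18024 CPM with vehicle, 36393 in replicate 1 and 25540 in replicate 2, and ND5 at 9848, 22289 and 10424. ND6 stood at 361 CPM with vehicle and 1091 ± 75.2 with No.10-3, and ATP8 at 249 and 480 ± 85.2. Cholesterol synthesis mRNAs had medians of 0.49 in replicate 1 and 0.28 in replicate 2, with 11 of 18 higher in both and 1 lower in both (camera adjusted p = 0.00999; adjusted p = 0.809 with an estimated correlation). ACAT2 stood at 5.50 CPM with vehicle and 20.3 ± 0.544 with No.10-3. SQLE, which encodes squalene epoxidase, stood at 17.9 CPM with vehicle, 32.0 in replicate 1 and 48.8 in replicate 2. SC5D stood at 18.8, 27.7 and 65.6, and CYP51A1 at 27.9, 37.0 and 86.0, so these members rose more in replicate 2. Targets of p53 and apoptosis genes had medians of 0.26 in replicate 1 and 0.44 in replicate 2, with 12 of 21 higher in both and 5 lower in both (camera adjusted p = 0.0359; adjusted p = 0.809 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21, stood at 75.1 CPM with vehicle and 149 ± 18.3 with No.10-3, and ZMAT3 at 39.8 and 110 ± 20.9. RRM2B, a p53-induced ribonucleotide reductase subunit, stood at 14.7 CPM with vehicle, 22.0 in replicate 1 and 73.1 in replicate 2. FAS was low throughout, at 1.83 CPM with vehicle and 3.77 ± 1.30 with No.10-3. This list also lost its call at a mean of at least 5 CPM (adjusted p = 0.0605, against 0.0291 to 0.0605 over its 6 alternatives).

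Small structured noncoding RNAs had a median of -0.0023 in replicate 1 and -1.89 in replicate 2, with 8 of 17 lower in both (camera adjusted p = 9.06e-07; adjusted p = 0.809 with an estimated correlation). SNORD3A, the U3 snoRNA of ribosomal RNA processing, stood at 9142 CPM with vehicle, 4047 in replicate 1 and 1022 in replicate 2. SCARNA2 stood at 926 CPM with vehicle, 491 in replicate 1 and 88.8 in replicate 2, SCARNA10 at 1158, 642 and 84.4, and SNORA73B at 3171, 2003 and 105. Cytosolic ribosomal protein mRNAs had medians of 0.11 in replicate 1 and -0.66 in replicate 2, with 21 of 73 lower in both and 37 on opposite sides of vehicle (camera adjusted p = 0.0308; adjusted p = 0.866 with an estimated correlation). RPL9 stood at 24.7 CPM with vehicle and 10.4 ± 0.565 with No.10-3, and RPL21 at 7.79 and 3.35 ± 0.718. RPS6 went the other way, at 326 CPM with vehicle and 690 ± 137 with No.10-3. These genes have many processed pseudogenes, so their counts are uncertain where reads map to several places.

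**Figure D2:**
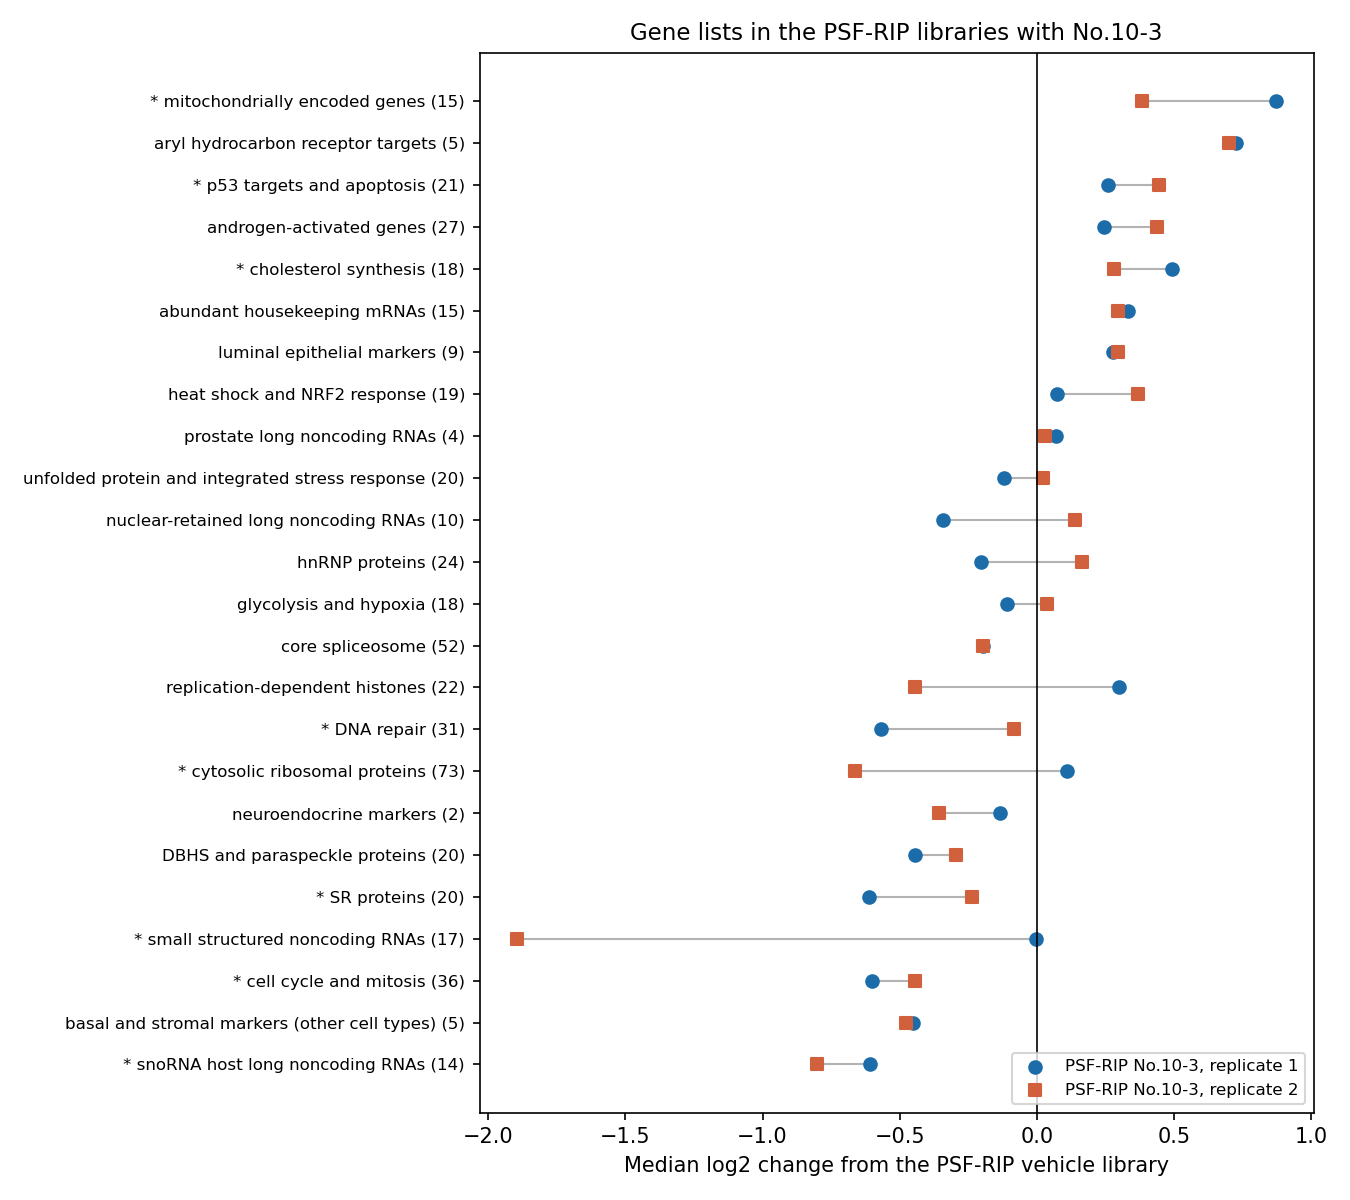
Median log2 change from the vehicle PSF-RIP library of 24 gene lists, with 1 point for each treated library, the number of tested members in parentheses and a star at the 9 lists that camera called with a preset correlation. The snoRNA host RNAs stood at -0.61 and -0.80 and mitochondrially encoded genes at 0.87 and 0.38, while small structured RNAs stood at -0.0023 and -1.89.

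The other 16 lists were not called by camera. Androgen-activated genes had a median log2 change of 0.37 (0.24 in replicate 1 and 0.44 in replicate 2, adjusted p = 0.0896), and their members went both ways. ACSL3 stood at 315 CPM with vehicle and 677 ± 284 with No.10-3, and KLK2, a prostate kallikrein, at 893 and 418 ± 77.5. PTGER4 stood at 2.29 CPM with vehicle and at 22.0 in replicate 1, but at 3.59 in replicate 2. The core spliceosome had a median of -0.16 (adjusted p = 0.232), hnRNP proteins 0.02 (-0.20 in replicate 1 and 0.16 in replicate 2, adjusted p = 0.754, with a median of -0.0054 under upper-quartile scaling) and replication-dependent histones -0.22 (0.30 in replicate 1 and -0.45 in replicate 2, adjusted p = 0.949). Heat shock and NRF2 response genes had a median of 0.20 (0.07 in replicate 1 and 0.37 in replicate 2, adjusted p = 0.209) and the unfolded protein and integrated stress response 0.06 (-0.12 in replicate 1 and 0.02 in replicate 2, adjusted p = 0.949). Glycolysis and hypoxia genes had a median of -0.06 (-0.11 in replicate 1 and 0.04 in replicate 2, adjusted p = 0.938) and abundant housekeeping mRNAs 0.35 (adjusted p = 0.182). The 5 measured aryl hydrocarbon receptor targets had a median of 0.63 (adjusted p = 0.209), among them TIPARP at 43.5 CPM with vehicle and 91.2 ± 6.31 with No.10-3 and, on the other side, AHRR at 8.70 with vehicle, 5.69 in replicate 1 and 3.86 in replicate 2.

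Nuclear-retained long noncoding RNAs had a median of 0.02 (-0.34 in replicate 1 and 0.14 in replicate 2, adjusted p = 0.991), which was -0.0032 under upper-quartile scaling, with NORAD, which is known as largely cytoplasmic, at 1146 CPM with vehicle and 2742 ± 306 with No.10-3 and TUG1 at 286 and 606 ± 153. The 4 measured prostate long noncoding RNAs had a median of 0.09 (0.07 in replicate 1 and 0.03 in replicate 2, adjusted p = 0.792). Among them CTBP1-AS, transcribed antisense to CTBP1, stood at 59.5 CPM with vehicle and 32.7 ± 0.965 with No.10-3, a value that is uncertain because the strand setting of the counting is not given. Luminal epithelial markers had a median of 0.27 (adjusted p = 0.447) and the 5 measured basal and stromal markers -0.57 (adjusted p = 0.262). Neuroendocrine markers rested on 2 measured genes, ENO2 and SYP, with a median of -0.25 (-0.13 in replicate 1 and -0.36 in replicate 2, adjusted p = 0.642). Test, median and mean differed in sign for 4 of these lists, the nuclear-retained RNAs, the prostate RNAs, the histones and the glycolysis genes. Over all 25 lists, 0 members passed the threshold, either over all genes or adjusted over the list alone.

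Change also varied with gene length, and differently in the 2 treated libraries. Protein-coding genes of 400 to 800 nt had a median log2 change of 0.37 in replicate 1 and -0.13 in replicate 2 (338 genes), while those over 6400 nt had -0.05 and 0.30 (1445 genes). Other genes of 100 to 200 nt, mostly snoRNAs and spliceosomal RNAs, had medians of -0.43 in replicate 1 and -2.81 in replicate 2 (122 genes), and those of up to 100 nt had -0.61 and -1.38 (130 genes).

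**Figure D3:**
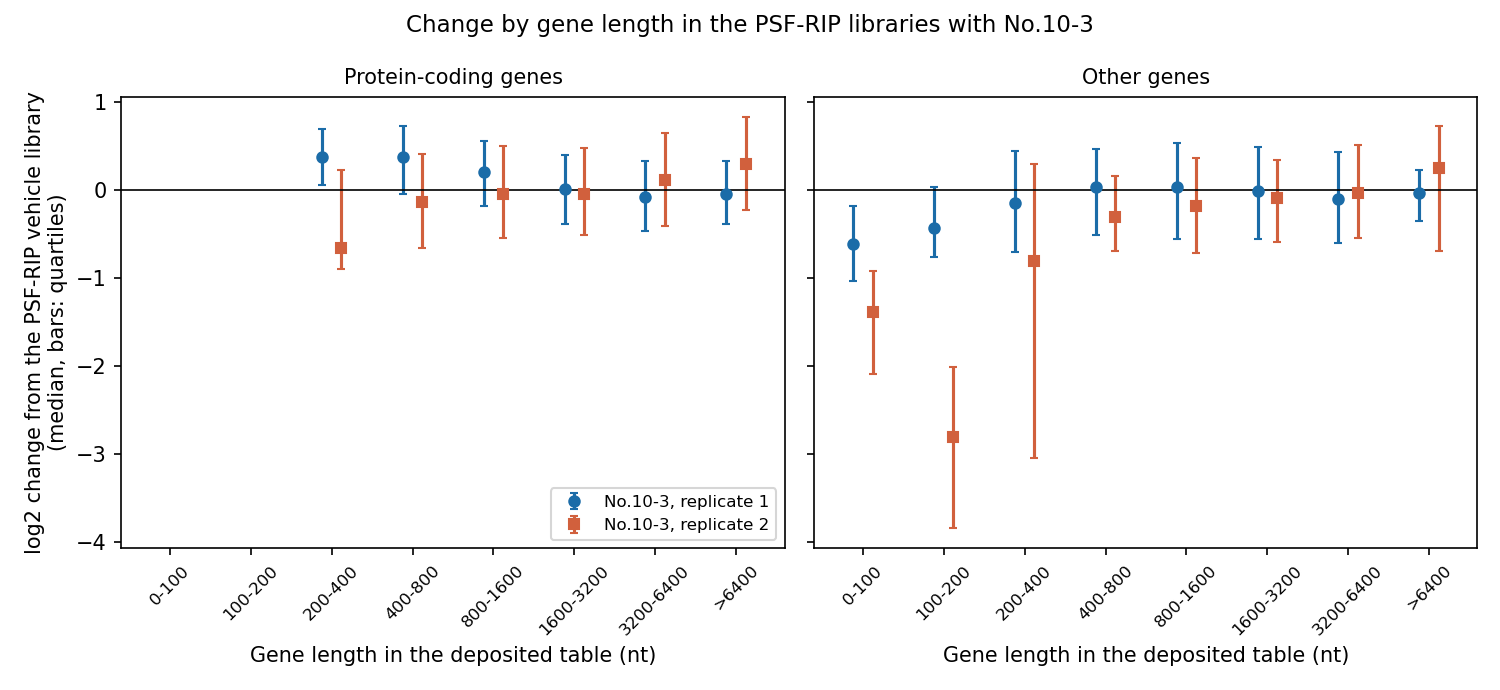
Log2 change from the vehicle PSF-RIP library (vertical axis) by gene length in nt (horizontal axis) for protein-coding genes and for other genes, with the median as a point and quartiles as bars in each treated library. Other genes of 100 to 200 nt stood at -2.81 in replicate 2 and -0.43 in replicate 1, while protein-coding genes over 6400 nt stood at 0.30 and -0.05.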

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

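The count of 0 called genes held under median-ratio and upper-quartile scaling, no filter, a filter at a mean of 5 CPM, DESeq2 and without mitochondrially encoded and small structured RNAs. With the length trend removed, chosen after seeing the data like the prior counts of 0.5 and 5, it became 19. That correction, set for snoRNAs by the shortest protein-coding genes, moved the snoRNA median from -1.30 to -1.55. Whether this made the calls was not tested. Genes at least 2-fold higher in both treated libraries numbered 352, but 209 with a prior count of 5, 1259 at 1.5-fold and 7 at 4-fold. Genes at least 2-fold lower in both numbered 210, but 360 without a filter, 94 at a mean of 5 CPM, 105 with a prior count of 5, 1016 at 1.5-fold and 5 at 4-fold. These follow from the genes tested, the shrinkage and the thresholds. Without one treated replicate the counts were 742 to 1476 higher and 878 to 1131 lower, since 1 library then decides each gene and no test remains. The 9 list calls became 0 with an estimated correlation, which leaves camera 1 residual degree of freedom and so hardly any chance of a call. Under the other settings 7 to 9 lists were called. DNA repair (median -0.22, adjusted p = 0.0816) and p53 targets (0.40, adjusted p = 0.0605) lost their calls at a mean of 5 CPM, with ranges over their alternatives of 0.0212 to 0.0816 and 0.0291 to 0.0605. The cause was not tested. Without mitochondrially encoded and small structured RNAs, those 2 lists had no members to test. Without one treated replicate the ribosomal protein median was -0.66 to 0.11, turning sign with replicate 1 alone. With the length trend removed it went from -0.24 to -0.40 (adjusted p from 0.0308 to 0.00482) and that of small structured RNAs from -0.47 to -0.76. Among lists that were never called, the median turned sign for nuclear-retained long noncoding RNAs with upper-quartile scaling (-0.0032) and with the length trend removed (-0.027), for hnRNP proteins with upper-quartile scaling (-0.0054), and without a filter for neuroendocrine markers (0.88) and basal and stromal markers (0.52), where genes with few counts entered. It also turned sign without replicate 2 for the nuclear-retained RNAs (-0.34), hnRNP proteins (-0.20), histones (0.30) and the unfolded protein response (-0.12), and without replicate 1 for glycolysis genes (0.037). Without one treated replicate the medians of heat shock and NRF2 genes (0.07 to 0.37), neuroendocrine markers (-0.36 to -0.13) and prostate RNAs (0.029 to 0.069, and 0.030 with the length trend removed) kept their sign. No paired analysis was possible because the groups compared share only replicate number 1. Comparisons that need the inputs, under any setting, were not run. Depth and the single vehicle library limit what can be seen. Among 13766 genes, edgeR recovered 1.6% of simulated 2-fold changes and 78.0% of 8-fold changes, all set in genes with a mean of at least 5 CPM. A count of 0 called genes therefore does not show that genes did not change.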

Other observations

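All tests of the snoRNA pattern, and the removal of the length trend used for the other patterns, were chosen only after the result was seen.

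Families of small RNA differed between the treated libraries beyond the list described above. Of 208 snoRNAs tested, 167 lay below vehicle in both treated libraries and 41 at least 2-fold below in both, while 0 lay at least 2-fold above in both. Among all 13766 tested genes, 4486 lay below in both and 210 at least 2-fold below, and the shared vehicle library gives such agreement without an effect. H/ACA box snoRNAs, which guide pseudouridylation, had a median log2 change of -0.51 in replicate 1 and -3.10 in replicate 2 (86 RNAs). C/D box snoRNAs, which guide 2'-O-methylation, had medians of -0.67 and -1.66 (122 RNAs). The 22 scaRNAs, which guide modification of spliceosomal RNAs, had medians of -0.45 and -2.62. Spliceosomal snRNAs had medians of 0.29 in replicate 1 and -1.94 in replicate 2 (12 RNAs), with 12 of 12 below vehicle in replicate 2 and 3 of 12 in replicate 1. RMRP, the RNA of RNase MRP, took 4.53% of counts with vehicle (95% Wilson interval 4.50 to 4.56%), 4.37% in replicate 1 (4.34 to 4.40%) and 0.650% in replicate 2 (0.642 to 0.659%). The 7 scaRNAs of 250 to 400 nt had medians of -0.85 and -3.61, with 7 of 7 lower in both, while 7SL, 7SK and RNase P RNAs, of like length, had medians of -0.33 and -0.49 (4 RNAs). Among single snoRNAs, SNORA71A had a log2 change of -1.69 in replicate 1 and -3.91 in replicate 2, and SNORD8 of -1.63 and -4.30. Both had an adjusted p of 0.140 by edgeR and were among the 19 genes called with the length trend removed. RMRP, SNORA71A and SNORD8 were chosen after their values were seen.

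As the first pattern, snoRNAs and scaRNAs were lower with No.10-3, mostly in replicate 2. In that library relative to replicate 1 they lay -1.91 log2 units from all other tested genes (medians -1.90 and 0.0049, quartiles -2.86 and -0.81 against -0.44 and 0.53). That gap is left unchanged by 1 factor per library, which argues against scaling as the whole cause. Nuclear-retained long noncoding RNAs, a list that includes the largely cytoplasmic NORAD, had a median log2 difference of 0.28 (quartiles 0.09 and 0.50). SnoRNAs had -1.78 (quartiles -2.85 and -0.75, two-sided permutation p = 4.1e-04), which argues against less nuclear RNA alone as the whole cause. Less nuclear RNA together with more polyadenylated RNA was not tested. In the same step scaRNAs of 250 to 400 nt lay -2.16 log2 units from all other genes of that length with a mean of at least 5 CPM, snoRNAs aside (medians -2.78 and -0.62, permutation p = 0.00138, 7 against 25 genes), which argues against a loss by length as their whole cause, although RMRP, among the 25, was at -2.97. For snoRNAs it stays open, since those of 100 to 160 nt lay only -0.12 from snRNAs of that length (medians -2.52 and -2.40, permutation p = 0.635, 94 against 11 RNAs). SnoRNAs under 100 nt fell less than those of 100 to 160 nt (medians -1.94 and -2.94, quartiles -3.07 and -0.85 against -3.88 and -2.29, permutation p = 4.9e-04, 26 against 64 RNAs with at least 20 CPM with vehicle). That comparison did not separate the snoRNA families, which differed themselves, with median log2 changes in replicate 2 of -3.10 (H/ACA box) and -1.66 (C/D box). It therefore cannot decide on a loss that grows as RNAs get shorter. More polyadenylated RNA in replicate 2 stays open too, since 45 other RNAs without a poly(A) tail had a median of -1.04 (quartiles -1.85 and -0.25) and went apart, with spliceosomal snRNAs at -2.30, histones at -0.92 and 7SL, 7SK and RNase P RNAs at -0.09. The effect of No.10-3, and the single vehicle library as a source of the median of -0.58 in replicate 1, remain untested.

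A second pattern is the gene lists on the same side of vehicle in both treated libraries. With the length trend removed, the snoRNA host RNAs had a median of -0.88 (camera adjusted p = 8.76e-04, over alternatives 8.76e-04 to 0.00279), cell cycle and mitosis -0.52 (7.09e-04, over alternatives 1.15e-04 to 7.85e-04) and cholesterol synthesis, which in replicate 2 was only at percentile 89.39 of random lists, 0.35 (0.00500, over alternatives 0.00500 to 0.0108). Those ranges are over scalings, filters, leaving out small RNAs and length removal, and with an estimated correlation all 3 lists had an adjusted p of 0.809. Mitochondrially encoded genes, which did not enter the fitted curve, had a median of 0.53 against 0.64 before. Their camera adjusted p was 0.00500 against 0.00298, and 0.809 with an estimated correlation. With the preset correlation, the values argue against gene length as the whole cause for the cell cycle and cholesterol synthesis lists. For the snoRNA host RNAs this cannot be decided, since the curve came from protein-coding genes. At 400 to 800 nt, other genes had medians of 0.03 in replicate 1 and -0.31 in replicate 2, against 0.37 and -0.13 for protein-coding genes. Deviations of the single vehicle library cannot be told apart from an effect of No.10-3, since 1 vehicle library serves both comparisons. Across all genes, the covariance of the comparisons lay -0.039 from that of simulated unchanged libraries (0.245 against a range of 0.270 to 0.298). The simulation thus gave more agreement than was observed and cannot decide the question. An effect of No.10-3 on these lists may remain, untested.

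As the last pattern, ribosomal protein mRNAs lay lower in replicate 2 than in replicate 1, with a median log2 difference of -0.72. With the length trend of protein-coding genes removed it was -0.25 (73 genes), so a trend with gene length may account for most of the difference between the replicates. These 73 genes were themselves among those that set the curve, so its removal is not an independent test of that trend. The same removal left the list lower than vehicle, with a median log2 change of -0.40 against -0.24 before (camera adjusted p = 0.00482 and 0.0308). No biological explanation was tested, since both libraries belong to 1 group.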
